A study of Mus musculus with 4 samples.

How the data were processed

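RNA was measured in 4 libraries of mouse bone marrow-derived dendritic cells, antigen-presenting cells grown from marrow of the C57BL/6 strain. Per the labels' protocols, the cells were cultured for 5 days with the cytokines GM-CSF and IL4. They were matured for 24 h with lipopolysaccharide (LPS) at 100 ng/ml and then transfected with an siRNA. The siRNA was si-Lnc-Dpf3, named for the long non-coding RNA lnc-Dpf3, or si-NC, against which it was set. Cells were left unstimulated or stimulated for 12 h with CCR7L, the 2 chemokines CCL19 and CCL21 that bind the receptor CCR7. Each of the 4 combinations was sequenced once, so there is 1 library per group. RNA was extracted with TRIzol and sequenced at Beijing Genomics Institute on the BGISEQ-500 platform, per the labels' protocols.

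The deposited table holds FPKM values (fragments per kilobase of transcript per 1e6 fragments) for 18021 genes with 2 decimals, per the file headers. The submitters' processing notes name Bowtie2, RSEM and the genome build GRCm38; versions and settings are not given in the sources used here. Gene-level read counts were not used here. The columns were matched to groups by the abbreviations in their names, read as the siRNA (nc or si) and the stimulation (un or tr), and every per-sample column was used. Genes carry Entrez numbers, and 17892 of them matched a RefSeq table of the mouse assembly GRCm38.p6, which supplied coordinates. Transcript length and GC content were medians over the GENCODE transcripts linked to each gene's RefSeq accessions. In 26 rows the symbol had been turned into a calendar date, and the symbol was restored through the Entrez number. All 4 columns differed from each other, 675 genes were listed at 0 in every library, and 751 rows held predicted transcripts alone. No row held a non-coding RefSeq transcript, so lnc-Dpf3 itself was not analysed here.

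Sequencing depth was estimated from the steps between low FPKM values of genes with a single transcript, since 1 read is worth a fixed FPKM at a given length. The estimates, in units of 1e6 reads, were 21.2 for si-NC unstimulated, 21.2 for si-NC with CCR7L, 21.1 for si-Lnc-Dpf3 unstimulated and 21.4 for si-Lnc-Dpf3 with CCR7L. At those depths 55.6%, 64.7%, 59.8% and 59.3% of 178, 190, 189 and 189 values lay within 0.1 of a whole read, against 20% by chance. Reads could therefore not be recovered gene by gene, and no count test was run. For the median transcript of 2819 bases, 1 FPKM corresponds to about 59 reads, 10 FPKM to about 588 and 100 FPKM to about 5877. Counting error at a 95% level then reaches ratios of 1.44-fold, 1.12-fold and 1.04-fold at these levels. These figures cover counting error only, not differences between cultures or library preparations.

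Values were analysed as log2(FPKM + 1), with a pseudocount of 1, over the 11041 genes with a mean of at least 1 FPKM in the 4 libraries. A log2 ratio on this scale understates the change of genes with low FPKM. Single comparisons between libraries carry no test, and genes at least 2-fold higher or lower were counted. The design written before the data were examined allowed for read counts or FPKM, and the branch for FPKM was followed. The only test was limma's moderated test in an additive model of siRNA and stimulation, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. This model has 1 residual degree of freedom, the interaction, and a median of 9.63 prior degrees of freedom borrowed across genes. It gives the average effect of each factor over the other and replicates no group. The p-values set each effect against the interaction and the borrowed spread, not against the spread between replicate cultures. A culture or preparation difference shared by both libraries of an siRNA or stimulation would enter the effect itself. In simulated data for the average knockdown effect, with 200 of 11041 genes changed, 91% were recovered at a log2 change of 0.5, 100% at 1 and 100% at 2. The false share of the calls there was 7.1%, 9.1% and 4.3%. Noise was drawn independently for each gene from limma's fitted prior, with no interaction, no length or GC trend and no shared culture difference. These shares hold only where the model's assumptions are met and do not describe the calls in the real libraries.

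Gene lists numbering 24 were fixed before the data were examined, and 23 had a measured member; the mitochondrially encoded list had none. For each list the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Lists outside the range from 2.5 to 97.5 are said to stand apart. For the 2 average effects, members past the limma test were counted over all genes and again adjusted over the list alone. The named genes were fixed by rule: the 10 highest and 10 lowest log2 ratios for CCR7L in si-NC cells and for si-Lnc-Dpf3 under CCR7L, and the 5 each way in the other 2 comparisons and the interaction. The rule added the 5 largest each way past the test in the average effects, up to 4 members of each list, and Dpf3, Ccr7, Hif1a and Ldha. Symbols of predicted genes, pseudogenes and small RNAs were left out of the ranking.

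The alternatives covered median-ratio scaling and equal totals, no filter or a mean of at least 10 FPKM, pseudocounts of 0.5 and 0.1, a 1.5-fold size rule, and random lists without matching. The test was also run without the mean-variance trend, with each factor alone, and with each factor alone and 1 library left out. A lowess trend on transcript length and then on GC content, with a span of 0.3, was removed from the ratios as a further alternative. Lengths were known for 10863 genes, 98.4% of those tested. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.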

Results

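Expression was profiled in LPS-matured mouse dendritic cells in a design crossing 2 siRNAs with 2 stimulations. Cells received si-NC or si-Lnc-Dpf3 and were left unstimulated or given the CCR7 ligands CCL19 and CCL21 for 12 h, with 1 library in each of the 4 groups. Summed FPKM was 492522 for si-NC unstimulated, 494419 for si-NC with CCR7L, 474610 for si-Lnc-Dpf3 unstimulated and 500607 for si-Lnc-Dpf3 with CCR7L. Between 10997 and 11075 genes reached 1 FPKM, and the top 10 genes held 9.5% to 10.3% of the summed FPKM. No group has a replicate, so differences between single libraries have no replicate check and carry no p-value.

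The siRNA targets lnc-Dpf3, a non-coding RNA that was not analysed here, so its depletion could not be checked in these values. Dpf3, the protein-coding gene on chromosome 12 (83213751 to 83487736, GRCm38) whose name lnc-Dpf3 carries, is not such a check. Dpf3 mRNA measured 0.93 FPKM in si-NC unstimulated, 2.03 in si-NC with CCR7L, 0.89 in si-Lnc-Dpf3 unstimulated and 1.35 in si-Lnc-Dpf3 with CCR7L. Averaged over both siRNAs, Dpf3 rose with CCR7L by a log2 change of 0.48 ± 0.12 (SE, limma adjusted p = 0.038). These values lie near the filter of 1 FPKM, where counting error alone reaches 1.44-fold for a transcript of median length. That figure is for a ratio of FPKM without the pseudocount, so it is not on the scale of the log2 change. Its average knockdown difference was -0.20 ± 0.12 (limma adjusted p = 0.43).

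The first comparison asked how the cells responded to CCR7 ligands under si-NC. Genes of the apolipoprotein L family, the enolase gene Eno3 and the class II transactivator gene Ciita were higher with CCR7L, and Hepacam2, Calcb and the gene of the inhibitory receptor PD-1 were lower. Apol7c on chromosome 15 (77524852 to 77533335) stood at 72.3 FPKM without and 368 FPKM with CCR7L, a ratio of 5.03 with the pseudocount of 1 added to both. Eno3, which encodes the muscle-type enolase of glycolysis, went from 13.0 to 53.2 FPKM, and Aif1, a marker of myeloid cells, from 8.96 to 39.5 FPKM. Log2 ratios were 2.33 for Apol7c, 2.02 for Aif1, 1.95 for Eno3, 1.80 for Apol10b, 1.74 for Apol7b, 1.66 for Slc46a3, 1.35 for Scn4b, 1.23 for the cyclin gene Ccnd1 and 1.19 for Gbp2b. At the low end, Hepacam2 had a log2 ratio of -2.50, Calcb -2.12, Pdcd1, which encodes PD-1, -2.12, Satb1 -1.61, Tmem151b -1.55, Wfdc9 -1.35, Tspan13 -1.32 and Crisp3 -1.31. Zbed5 had a log2 ratio of -2.58 that rests on 1 library, since its FPKM was 6.62 in si-NC unstimulated and 0.27, 0.30 and 0.15 elsewhere. The near-identical copies Tmem254c (log2 ratio 3.53) and Tmem254b (-3.78) moved apart while the summed FPKM of 3 copies was 20.3 without and 19.9 with CCR7L, so both values are uncertain. Of 11041 genes, 21 were at least 2-fold higher and 29 at least 2-fold lower.

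The same contrast under si-Lnc-Dpf3 gave a closely similar list of leading genes. Apol7c measured 74.2 FPKM without and 341 FPKM with CCR7L, and Eno3 12.5 and 53.1 FPKM. Log2 ratios were 2.18 for Apol7c, 1.90 for Aif1, 1.51 for Apol7b, -2.49 for Hepacam2, -2.03 for Calcb, -1.64 for Pdcd1 and -1.52 for Satb1. Tmem254c at 3.44 and Tmem254b at -2.75 were again uncertain. In si-Lnc-Dpf3 cells 21 genes were at least 2-fold higher and 32 lower, or 13 and 35 after scaling to equal totals. These 2 comparisons share no library. Among 50 genes at least 2-fold different under si-NC, 49 had the same sign under si-Lnc-Dpf3. At least 2-fold different in both with the same sign were 33 genes, against 0.12 for independent lists. Across genes, which are not independent replicates, the ratios correlated with a Pearson r of 0.602 and a Spearman rho of 0.33.

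**Figure D1:**
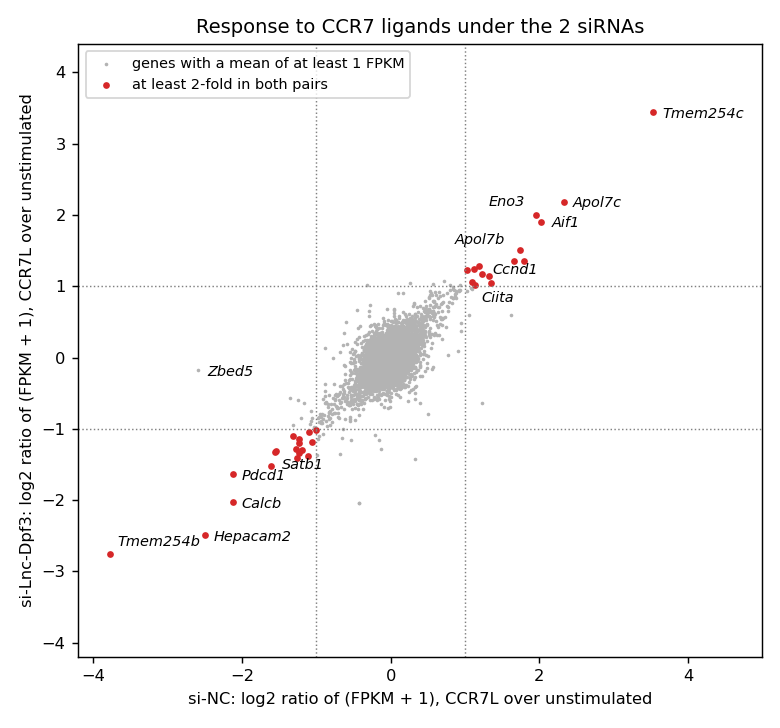
Log2 ratio of (FPKM + 1) with CCR7L over unstimulated in si-NC cells (x axis) and si-Lnc-Dpf3 cells (y axis), 1 point per gene, with dotted lines at 2-fold. Red points mark the 33 genes at least 2-fold different in both, all with the same sign, while Zbed5 departs under si-NC alone.

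Averaged over both siRNAs, CCR7L raised 324 genes and lowered 343 of 11041 (limma, adjusted p under 0.05). Apol7c rose by a log2 change of 2.26 ± 0.07 (SE, limma adjusted p = 2.5e-08), Eno3 by 1.98 ± 0.07 and Aif1 by 1.96 ± 0.07. Apol7b rose by 1.63 ± 0.11, whereas Hepacam2 changed by -2.50 ± 0.10, Calcb by -2.08 ± 0.08, Pdcd1 by -1.88 ± 0.13 and Satb1 by -1.56 ± 0.08. The tests for Tmem254c (3.49) and Tmem254b (-3.26) passed as well, with the uncertainty of near-identical copies. With median-ratio scaling 516 rose and 404 fell, and with the stimulation as the only factor 238 genes passed. Leaving out 1 library from that single-factor fit gave 170 genes without si-NC unstimulated, 112 without si-NC with CCR7L, 151 without si-Lnc-Dpf3 unstimulated and 89 without si-Lnc-Dpf3 with CCR7L, and the additive model in limma gave 0 without a filter on low genes (1867 at an unadjusted p under 0.05).

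Antigen presentation genes had the highest list median for CCR7L under si-Lnc-Dpf3 and in the average effect, while cholesterol synthesis ranked first under si-NC. Of 22 measured, 10 rose and 0 fell in the average effect (limma, over all genes), and 12 rose when adjusted over the list alone. The list median was 0.17 under si-NC and 0.30 under si-Lnc-Dpf3, both at percentile 100.0 of random matched lists. Ciita, the transactivator of class II genes, rose by 1.08 ± 0.08, the peptide-loading gene H2-DMb2 by 0.98 ± 0.07, and the class II chain genes H2-Ab1 by 0.79 ± 0.08 and H2-Eb1 by 0.77 ± 0.08. Ciita went from 9.65 to 21.8 FPKM under si-NC and from 9.34 to 20.5 under si-Lnc-Dpf3.

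Cholesterol synthesis genes were also higher with CCR7L, with list medians of 0.24 under si-NC and 0.13 under si-Lnc-Dpf3, both at percentile 100.0, the latter median becoming 0.06 with equal totals. In the average effect 7 of 22 rose and 1 fell, or 10 and 1 adjusted over the list alone. Idi1 rose by 0.33, Hmgcs1 by 0.32, Acat2 by 0.31 and Mvd by 0.30, while Pmvk fell with a log2 change of -0.25.

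Among 24 maturation and costimulation genes, 2 rose and 6 fell with CCR7L, or 5 and 6 adjusted over the list alone. Cd83, a marker of mature dendritic cells, had an average log2 change of -0.71 ± 0.06 and the tryptophan-degrading enzyme gene Ido1 -0.63 ± 0.10. The chemokine gene Ccl17 rose by 0.63 ± 0.12. Ccl22 measured 3746 and 5145 FPKM under si-NC and 3040 and 4714 under si-Lnc-Dpf3, but its average log2 ratio of 0.55 did not pass (limma adjusted p = 0.093). Medians of this list, 0.01 and 0.03, take the opposite sign after scaling to equal totals.

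Migration and adhesion genes went both ways, with 2 of 38 rising and 5 falling, or 3 and 5 adjusted over the list alone. The actin-bundling gene Fscn1 rose by 0.57 ± 0.10, while Cxcr4 changed by -0.61 ± 0.07, S1pr1 by -0.51 ± 0.10 and Itga4 by -0.39 ± 0.08. Ccr7, which encodes the receptor of both ligands, measured 808 and 681 FPKM under si-NC and 685 and 615 FPKM under si-Lnc-Dpf3. Its average CCR7L log2 ratio of -0.20 ± 0.09 did not pass (limma adjusted p = 0.29). List medians were -0.02 under si-NC and -0.03 under si-Lnc-Dpf3, the latter at percentile 0.73, which became 59.9 with the length and GC trend removed and 44.4 against random lists without matching.

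Immediate early genes, which respond early to signals, included 2 of 26 that rose and 4 that fell, with the same counts adjusted over the list alone. The nuclear receptor gene Nr4a2 had an average log2 change of -1.03 ± 0.10, Nr4a3 -0.47 ± 0.07 and Fosl2 -0.46 ± 0.07, while the phosphatase gene Dusp2 rose by 0.57 ± 0.09. No inflammatory cytokine or chemokine gene of 30 passed the limma test for CCR7L, over all genes or adjusted over the list alone. Their median was -0.08 under si-NC (percentile 0.3) and 0.03 under si-Lnc-Dpf3 (percentile 43.2), the latter turning negative with equal totals. In the NF-kappaB feedback list 1 of 15 fell, Rel at -0.37 ± 0.09, and the count was also 1 adjusted over the list alone. Medians there were -0.10 (percentile 0.29) and -0.03 (percentile 12.3). Of 35 interferon response genes, 2 rose with CCR7L, Ifi35 by 0.25 and Ifi205 by 0.24, with the same number adjusted over the list alone.

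Markers of other cells were read beside the CCR7L groups, and 0 of 9 mast cell and basophil and 0 of 4 erythroid and stromal markers passed limma in the average effect, over all genes or adjusted over the list alone. Mast cell and basophil markers had a median of -0.10 under si-NC (percentile 2.4, and 2.6 to 5.06 in 5 alternatives) and 0.03 under si-Lnc-Dpf3, the latter turning negative with equal totals. The 4 erythroid and stromal markers had medians of -0.20 (percentile 2.27) and 0.07 (percentile 89.9). Among 11 conventional dendritic cell markers 1 rose and 2 fell in the average effect, or 2 and 4 adjusted over the list alone. Dpp4 rose by 0.56, while Kit changed by -0.38 and Zbtb46 by -0.34.

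**Figure D2:**
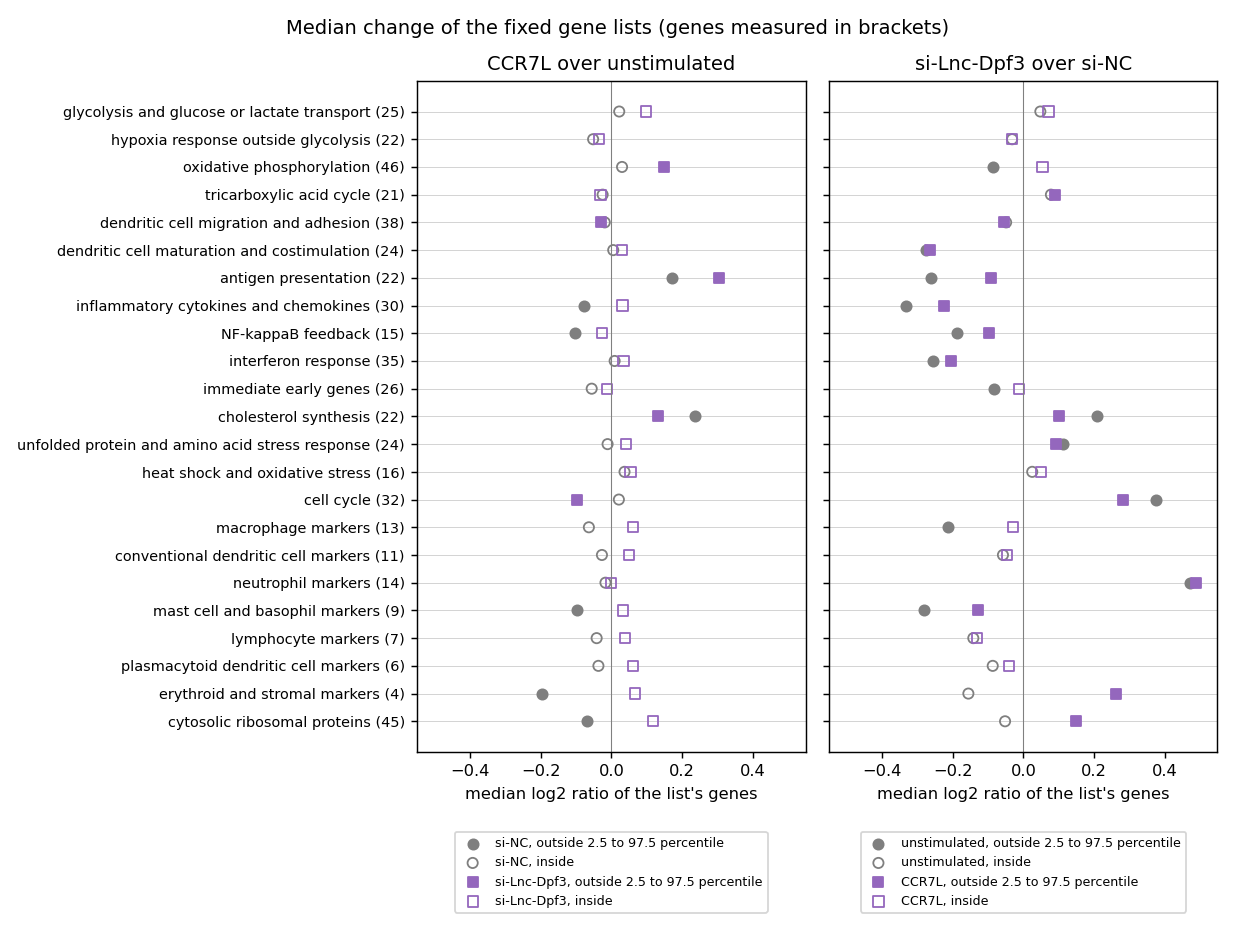
Median log2 ratio of each fixed gene list (x axis) for CCR7L over unstimulated (left, by siRNA) and si-Lnc-Dpf3 over si-NC (right, by stimulation), with filled points outside the central 95% of random matched lists. Antigen presentation has the highest CCR7L median under si-Lnc-Dpf3 (0.30), and neutrophil markers the highest knockdown medians (0.49 with CCR7L and 0.47 unstimulated); medians near 0 can change sign with the scaling.

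The comparison of si-Lnc-Dpf3 with si-NC under CCR7L asked what the knockdown changed in stimulated cells, and in particular whether glycolysis genes differed. Among the 10 named genes with the highest ratios, Elane, Ltf and Ngp belong to the fixed neutrophil list. The lowest ratio among genes kept by the naming rule was that of Ifit1bl1. Elane, the neutrophil elastase gene on chromosome 10 (79886312 to 79888216), measured 17.0 FPKM under si-NC and 35.4 FPKM under si-Lnc-Dpf3, a ratio of 2.02 with the pseudocount. Log2 ratios were 1.08 for Lrg1, 1.01 for Elane, 0.94 for the lactoferrin gene Ltf, 0.90 for Ceacam10, 0.83 for the granule protein gene Ngp, 0.78 for Septin5, 0.74 for the neutrophil antigen gene Cd177, 0.73 for Tmem216 and 0.69 for Fcnb. Tmem254b, at 0.72, is 1 of the near-identical copies. Lower were Ifit1bl1 (-1.10), Insl3 (-0.95), the hepcidin gene Hamp (-0.95), Ifi205 (-0.89), Ms4a4c (-0.77), Nudt6 (-0.76), Tal2 (-0.76), the interleukin gene Il1f6 (-0.75), Serpina3b (-0.75) and Rpl37rt (-0.68). Of 11041 genes, 4 were at least 2-fold higher and 4 lower, or 2 and 4 after scaling to equal totals or by median ratio. Insl3, Nudt6, Tal2 and Serpina3b lay below 3 FPKM in all 4 libraries, where counting error alone is large.

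Unstimulated cells gave a related picture. Ltf measured 74.1 FPKM under si-NC and 155 FPKM under si-Lnc-Dpf3, and Ngp 687 and 1233 FPKM. Log2 ratios were 1.05 for Ltf, 0.90 for Ceacam10, 0.89 for Clec4b2 and 0.84 for Ngp, and the histone gene Hist1h2ao stood at 1.06. At the low end were Zbed5 (-2.55, from the single si-NC unstimulated value), Ifit1bl1 (-1.21), Hamp (-1.20), Gstt4 (-1.06) and the acute-phase gene Orm1 (-1.04). Counts at 2-fold were 4 higher and 6 lower of 11041. This comparison shares no library with that under CCR7L, and all 8 genes at least 2-fold different there had the same sign here. A culture or transfection difference between the si-NC and si-Lnc-Dpf3 cells could still enter both ratios alike. The ratios correlated across genes with a Pearson r of 0.444 and a Spearman rho of 0.368, and 1 gene was at least 2-fold different in both.

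**Figure D3:**
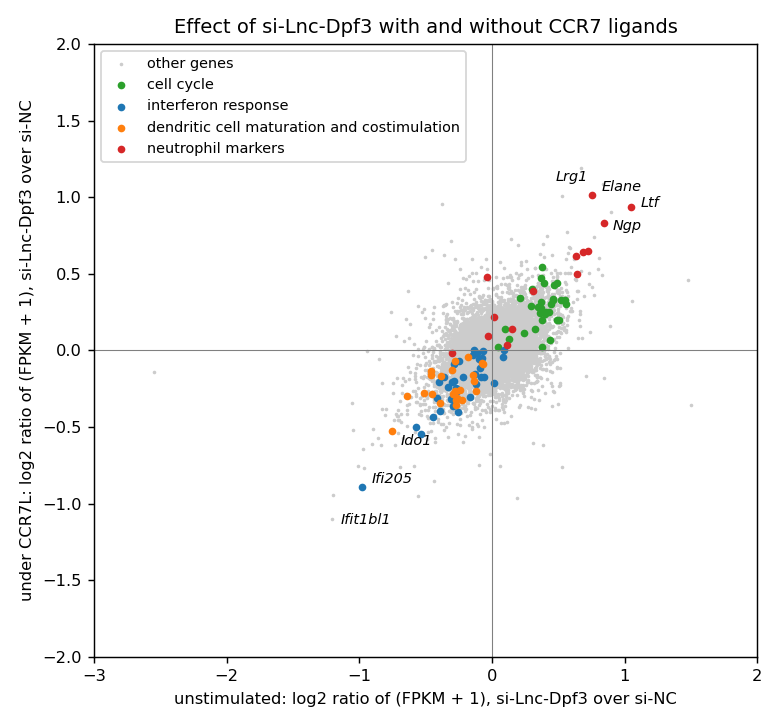
Log2 ratio of (FPKM + 1) of si-Lnc-Dpf3 over si-NC in unstimulated cells (x axis) and under CCR7L (y axis), 1 point per gene, with 4 fixed lists in colour. All 32 cell cycle genes lie above 0 on both axes, and all 24 maturation and costimulation genes lie below 0 on both.

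In the average knockdown effect over both stimulations, 257 genes rose and 225 fell of 11041 (limma, adjusted p under 0.05). Ltf rose by a log2 change of 0.99 ± 0.06 (SE, limma adjusted p = 6.4e-05), Lrg1 by 0.96 ± 0.09, Ceacam10 by 0.90 ± 0.09, Elane by 0.89 ± 0.08 and Ngp by 0.84 ± 0.10. Ifit1bl1 changed by -1.16 ± 0.06 (limma adjusted p = 2.9e-05), Hamp by -1.07 ± 0.10, Ifi205 by -0.94 ± 0.06, Il1f6 by -0.88 ± 0.10 and Ms4a4c by -0.87 ± 0.07. These calls depend on the additive model, since 1 gene passed with the siRNA as the only factor (1152 at an unadjusted p under 0.05), 77 without the mean-variance trend, 788 with median-ratio scaling (354 higher and 434 lower), and 0 in limma without a filter on low genes (1808 unadjusted). The single-factor fit in limma gave 0 genes with any 1 of the 4 libraries left out, with 520 at an unadjusted p under 0.05 without si-NC unstimulated, 603 without si-NC with CCR7L, 798 without si-Lnc-Dpf3 unstimulated and 1445 without si-Lnc-Dpf3 with CCR7L, and the counts by list given next carry the same limit.

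Neutrophil markers formed the group with the highest knockdown median, 0.49 under CCR7L and 0.47 in unstimulated cells, both at percentile 100.0. Of 14 measured, 6 rose and 0 fell in the average effect, or 8 and 0 adjusted over the list alone. The proteinase gene Prtn3 rose by 0.69 ± 0.06, the cathelicidin gene Camp by 0.66 ± 0.06 and the myeloperoxidase gene Mpo by 0.35 ± 0.07. The abundant S100a8 measured 3020 and 3269 FPKM in the si-NC libraries and 4691 and 5022 in the si-Lnc-Dpf3 libraries, with an average log2 ratio of 0.63 ± 0.16 that did not pass (limma adjusted p = 0.054). Lcn2, at 1540 to 1641 FPKM in all 4 libraries, had a ratio of 0.03. With CCR7L the neutrophil markers had medians of -0.02 under si-NC and 0.00 under si-Lnc-Dpf3, the latter changing sign with the scaling, and 0 of 14 passed, over all genes or adjusted over the list alone.

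All 32 cell cycle genes were higher with si-Lnc-Dpf3 in both stimulations, with medians of 0.28 under CCR7L and 0.38 in unstimulated cells, at percentile 100.0 in each. Averaged over both stimulations 21 rose and 0 fell, or 28 and 0 adjusted over the list alone. Ccnb2 rose by 0.47 ± 0.07, Aurkb by 0.46 ± 0.07, Plk1 by 0.45 ± 0.07 and Kif11 by 0.44 ± 0.08, genes of mitotic entry and the spindle. The higher neutrophil marker median of 0.46 in the average effect stands beside this group. With CCR7L the cell cycle median was 0.02 under si-NC and -0.10 under si-Lnc-Dpf3, and 1 of 32 passed (adjusted over the list alone, also 1), Ccnd1, which rose by 1.20 ± 0.08.

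All 24 maturation and costimulation genes were lower with si-Lnc-Dpf3 in both stimulations, with medians of -0.26 under CCR7L and -0.28 in unstimulated cells at percentile 0.0. Averaged over both stimulations 0 rose and 11 fell, or 0 and 19 adjusted over the list alone. Ido1 had an average log2 change of -0.64 ± 0.10, the costimulatory receptor gene Cd40 -0.39 ± 0.07, Tnfsf4 -0.37 ± 0.06 and Cd86 -0.27 ± 0.06. Ccl17 measured 1257 and 1727 FPKM under si-NC and 808 and 1402 under si-Lnc-Dpf3, with an average of -0.47 ± 0.12 that did not pass (limma adjusted p = 0.051). Neutrophil markers were higher in the same libraries, with an average median of 0.46.

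Interferon response genes were lower with si-Lnc-Dpf3 in 33 of 35 cases under CCR7L (median -0.20) and in 32 of 35 in unstimulated cells (median -0.26), both at percentile 0.0. Across both stimulations 0 rose and 14 fell, or 0 and 20 adjusted over the list alone. Rsad2, an antiviral gene, had an average log2 change of -0.54 ± 0.07, the chemokine gene Cxcl10 -0.53 ± 0.07 and Ifit3 -0.44 ± 0.06. Inflammatory cytokine and chemokine genes had medians of -0.22 and -0.33, both at percentile 0.0, and 0 of 30 rose and 9 fell, or 0 and 22 adjusted over the list alone. The serum amyloid gene Saa3 changed by -0.76 ± 0.12, Nos2 by -0.62 ± 0.07, the IL-12 subunit gene Il12a by -0.58 ± 0.08 and Ccl7 by -0.57 ± 0.08. Of 15 NF-kappaB feedback genes 0 rose and 2 fell, Socs3 at -0.43 ± 0.07 and Tnfaip3 at -0.29 ± 0.06, or 0 and 3 adjusted over the list alone. Their medians were -0.10 under CCR7L and -0.19 in unstimulated cells. The same libraries had higher neutrophil markers, with an average median of 0.46.

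Antigen presentation genes had knockdown medians of -0.09 under CCR7L (percentile 0.1) and -0.26 in unstimulated cells (percentile 0.0). In the average effect 0 of 22 rose and 2 fell, with the same counts adjusted over the list alone, namely the protease gene Ctss at -0.37 ± 0.09 and H2-DMb1 at -0.29 ± 0.07. The class I genes H2-D1 and H2-K1 had average ratios of -0.27 and -0.27 that did not pass (limma adjusted p = 0.25 and 0.27). Both stood at 1630 FPKM in si-NC unstimulated, and as close paralogs they are uncertain. Migration and adhesion genes had medians of -0.05 under CCR7L (percentile 0.42) and -0.05 in unstimulated cells (percentile 24.3), the latter turning positive with equal totals. Of 38, 0 rose and 5 fell, or 1 and 6 adjusted over the list alone. Among those that fell were the protease genes Mmp12 (-0.45 ± 0.07) and Mmp13 (-0.32 ± 0.08) and the integrin gene Itgax (-0.35 ± 0.07). The average knockdown ratio of Ccr7 was -0.19 ± 0.09 and did not pass (limma adjusted p = 0.3).

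Cholesterol synthesis genes were higher with si-Lnc-Dpf3, with medians of 0.10 under CCR7L (percentile 99.4) and 0.21 in unstimulated cells (percentile 100.0). In the average effect 3 of 22 rose and 0 fell, or 10 and 1 adjusted over the list alone, with Hsd17b7 rising by 0.37 ± 0.09 and Fdps by 0.36 ± 0.06. The unfolded protein and amino acid stress list had medians of 0.09 and 0.11, and 3 of 24 rose and 1 fell, or 5 and 1 adjusted over the list alone. The serine synthesis genes Phgdh and Psat1 rose by 0.40 ± 0.06 and 0.36 ± 0.06, while the stress factor gene Ddit3 changed by -0.32 ± 0.07. Immediate early genes included 2 of 26 that rose, Myc by 0.40 ± 0.07 and Klf2 by 0.34 ± 0.08, and 1 that fell, Atf3 at -0.31 ± 0.06, or 2 and 2 adjusted over the list alone. Their median was -0.01 under CCR7L and -0.08 in unstimulated cells.

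Markers of other cells were read beside these groups. Conventional dendritic cell markers had knockdown medians of -0.05 under CCR7L and -0.06 in unstimulated cells, and 0 of 11 rose and 2 fell in the average effect, Itgax and Irf8 (-0.29 ± 0.07), with the same counts adjusted over the list alone. Macrophage markers had medians of -0.03 and -0.21, the latter at percentile 0.08 and at 5.92 with the length and GC trend removed. In that list 0 of 13 rose and 3 fell, or 2 and 5 adjusted over the list alone, with Adgre1 at -0.33 ± 0.07 and Msr1 at -0.31 ± 0.07. Mast cell and basophil markers had medians of -0.13 and -0.28, and 0 of 9 rose and 2 fell, or 0 and 3 adjusted over the list alone, with Hdc at -0.36 ± 0.07 and Fcer1a at -0.33 ± 0.08.

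Glycolysis and glucose or lactate transport genes differed little with si-Lnc-Dpf3. Their median was 0.07 under CCR7L (percentile 96.3) and 0.05 in unstimulated cells (percentile 96.9), with 18 and 14 of 25 higher and 0 at least 1.5-fold different. The unstimulated median became 0.01 with median-ratio scaling and 0.10 with equal totals. In the average knockdown effect 0 of 25 passed limma, over all genes or adjusted over the list alone. The largest differences under CCR7L were 0.28 for Pfkfb4, 0.25 for Gpi1, 0.19 for the lactate transporter gene Slc16a1 and -0.18 for Eno2. Ldha, the lactate dehydrogenase gene, measured 462 and 469 FPKM under si-NC and 444 and 485 FPKM under si-Lnc-Dpf3. Hif1a mRNA, which encodes the hypoxia-inducible factor, measured 71.0 and 71.9 FPKM under si-NC and 74.0 and 67.4 FPKM under si-Lnc-Dpf3. Knockdown averages were 0.00 ± 0.08 for Ldha and -0.02 ± 0.07 for Hif1a (limma adjusted p = 0.99 and 0.94). The average median of 0.07 stood at percentile 99.3. This became 92.4 with the length and GC trend removed, 92.9 among genes with a mean of at least 10 FPKM and 96.9 against random lists without matching.

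With CCR7L the glycolysis list had a median of 0.02 under si-NC and 0.10 under si-Lnc-Dpf3, the latter becoming 0.02 with equal totals. In the average effect 2 of 25 rose, Eno3 and Pfkfb3 (0.29 ± 0.06), or 2 adjusted over the list alone. Hypoxia-responsive genes outside glycolysis had CCR7L medians of -0.05 and -0.04, and 1 of 22 rose and 4 fell, with the same counts adjusted over the list alone. The growth factor gene Vegfa had an average log2 change of -0.91 ± 0.07, Mxi1 -0.76 ± 0.06, Ndrg1 -0.29 ± 0.06 and Bhlhe40 -0.28 ± 0.07. In the knockdown comparisons their median was -0.03 in both, the unstimulated 1 turning positive with equal totals. The average knockdown median was -0.06 at percentile 0.89, or 4.22 among genes with a mean of at least 10 FPKM, and 0 of 22 passed, over all genes or adjusted over the list alone.

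The interaction, the CCR7L log2 ratio under si-Lnc-Dpf3 minus that under si-NC, asked whether the knockdown altered the response to the ligands. It was at least 1 in size for 7 genes upward and 9 downward of 11041, or 4 and 9 after scaling to equal totals. With a mean of at least 10 FPKM required, 0 genes upward and 1 downward remained. Among genes kept by the naming rule, highest were Zbed5 (2.41, from the single si-NC unstimulated value), Rsc1a1 (1.11), the uncertain Tmem254b (1.02), Cd8b1 (1.02) and Cxx1c (1.01). Lowest among them were Nudt6 (-1.29), Tram2 (-1.03), Zfp966 (-0.85), Tal2 (-0.82) and Art2b (-0.73). Across genes the standard deviation of the interaction divided by 2 was 0.097, against 0.193 for the average CCR7L effect and 0.154 for the average knockdown effect. The 4 libraries allow no test of the interaction beside both factors. Fitted alone in limma, with both larger average effects left in its noise term, it gave 0 genes (57 at an unadjusted p under 0.05), which leaves open whether any response was altered. The list medians were 0.19 for antigen presentation (percentile 100.0), 0.13 for oxidative phosphorylation (percentile 100.0), 0.18 for cytosolic ribosomal proteins (percentile 99.99), 0.09 for glycolysis (percentile 88.2) and -0.12 for cell cycle genes (percentile 0.0). With equal totals these medians became 0.12, 0.06, 0.11, 0.02 and -0.19 in the same order. Medians were 0.47 for 4 erythroid and stromal markers (percentile 100.0), 0.17 for mast cell and basophil markers (percentile 98.9), 0.12 for inflammatory cytokines and chemokines (percentile 97.7) and -0.01 for migration and adhesion genes (percentile 1.08). Removing the length and GC trend left 0.08 for antigen presentation, -0.07 for cell cycle genes and 0.28 for erythroid and stromal markers. It left 0.08 for mast cell and basophil markers (percentile 97.46), 0.03 for the inflammatory list (percentile 90.2) and 0.00 for migration and adhesion (percentile 69.2). These last lists then no longer stood apart.

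Ratios involving the si-Lnc-Dpf3 unstimulated library varied most with transcript length, while all 4 comparisons varied with GC content. In the CCR7L comparison under si-Lnc-Dpf3 the median log2 ratio was 0.13 in the shortest 10% of genes (median length 885 bases) and -0.18 in the longest 10% (7297 bases). Under si-NC the same medians were -0.01 and 0.00. Across genes, Spearman rho with length was -0.465 for CCR7L under si-Lnc-Dpf3, 0.358 for the knockdown in unstimulated cells, -0.119 for the knockdown under CCR7L and 0.011 for CCR7L under si-NC. With GC content rho was 0.274, -0.221, 0.267 and -0.219 in the same order, and 0.437 for the interaction. For the average CCR7L effect rho was -0.32 with length and 0.069 with GC content. For the average knockdown effect it was 0.181 and -0.011, and for the interaction rho with length was -0.461. The limma tests were run on values with the trend left in, so it can enter their calls. Oxidative phosphorylation genes had CCR7L medians of 0.03 under si-NC and 0.15 under si-Lnc-Dpf3, and knockdown medians of 0.05 under CCR7L and -0.09 in unstimulated cells. The oxidative phosphorylation median in the average CCR7L effect was 0.12 at percentile 100.0. Cytosolic ribosomal protein genes had CCR7L medians of -0.07 under si-NC (percentile 0.0) and 0.12 under si-Lnc-Dpf3. Their knockdown medians were 0.15 under CCR7L and -0.05 in unstimulated cells, the last turning positive with equal totals. In both average effects 0 of 46 and 0 of 45 genes passed limma, over all genes or adjusted over the list alone. With the length and GC trend removed, the oxidative phosphorylation medians for CCR7L under si-Lnc-Dpf3 and for the knockdown in unstimulated cells became 0.01 (percentile 70.1) and 0.03 (percentile 80.9), and the ribosomal medians for the same comparisons became -0.04 and 0.09. The ribosomal knockdown median under CCR7L, at percentile 100.0, was 0.11 after removal and stayed outside the central 95% of random lists. So did the ribosomal CCR7L median under si-NC, at -0.06, and the oxidative phosphorylation median in the average CCR7L effect, at 0.04. The interaction medians then were -0.04 for oxidative phosphorylation (percentile 2.38) and 0.01 for ribosomal proteins (percentile 62.6).

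**Figure D4:**
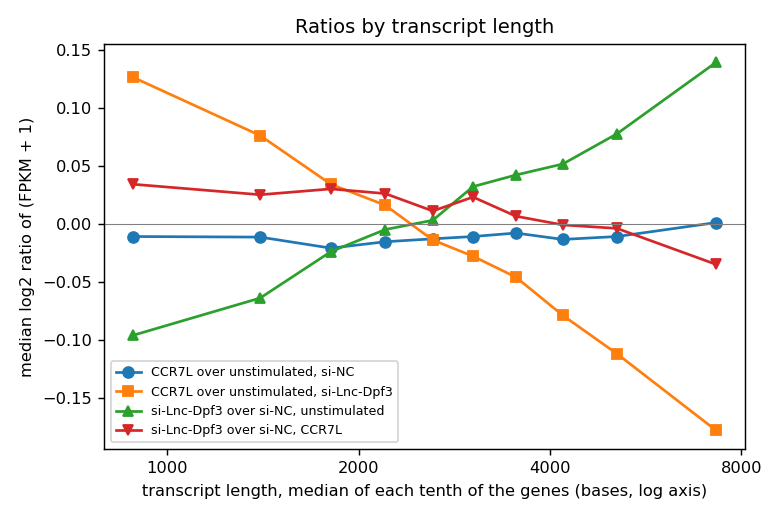
Median log2 ratio of (FPKM + 1) (y axis) in 10 equal groups of genes ordered by transcript length (x axis, bases, log scale) for the 4 comparisons of single libraries. The 2 comparisons that use the si-Lnc-Dpf3 unstimulated library slope in opposite directions, from 0.13 to -0.18 and from -0.10 to 0.14.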

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

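Pseudocount 0.1, the fit without a mean-variance trend, the fits with 1 library left out, the removal of the length and GC trend, and the agreement without a filter or at pseudocount 0.1 were chosen after seeing the data. Genes at least 2-fold different, main counts 50 (CCR7L, si-NC), 53 (CCR7L, si-Lnc-Dpf3), 8 (knockdown, CCR7L), 10 (knockdown, unstimulated) and 16 (interaction), became, in that order, 15, 23, 3, 3 and 1 at a mean of at least 10 FPKM, where fewer genes enter, 93, 115, 22, 27 and 44 with pseudocount 0.1, and 209, 264, 59, 113 and 90 by a 1.5-fold rule. Pseudocount 0.5 gave 13 for the knockdown under CCR7L, and no filter gave 32 for the interaction. The average CCR7L effect called 667 genes, 238 with the factor alone, 920 with median-ratio scaling (516 higher and 404 lower, against 324 and 343), 0 in limma without a filter (1867 unadjusted) and 89 to 170 with the factor alone and 1 library left out (89 without si-Lnc-Dpf3 with CCR7L, 112 without si-NC with CCR7L, 151 without si-Lnc-Dpf3 unstimulated, 170 without si-NC unstimulated). The average knockdown effect called 482, 788 with median-ratio scaling (354 higher and 434 lower, against 257 and 225), of which 481 were shared, 77 without the mean-variance trend, 1 with the factor alone (1152 unadjusted), 0 in limma without a filter (1808 unadjusted) and 0 with the factor alone and any 1 of the 4 libraries left out (520 to 1445 unadjusted). With 3 libraries the additive model leaves no residual degree of freedom, so the fits with 1 left out compare with 238 and 1, not with 667 and 482. Where a library is left out, a lone sample is assumed to vary like the others. Pearson r between the CCR7L ratios, 0.602, was 0.641 at a mean of at least 10 FPKM and 0.524 without a filter. For the knockdown ratios, 0.444, it was 0.553 and 0.357, 0.423 with pseudocount 0.5 and 0.397 with 0.1. The cause of these shifts was not tested. Of 68 list medians outside the central 95% of random lists, 66 stayed outside on the same side with median-ratio scaling, 67 with equal totals, 62 without matching, 58 of 64 at a mean of at least 10 FPKM and 55 with the length and GC trend removed, where 12 were lost and 1 reversed. That was the oxidative phosphorylation interaction, from percentile 100.0 to 2.38. No log2 ratio of the 90 named values changed sign under the scalings or pseudocounts tried, and 32 moved beyond counting error with pseudocount 0.1. The edgeR test and TMM normalization planned for read counts were not run, nor was DESeq2, since all of these need read counts. Depth limits genes near 1 FPKM, where counting error alone reaches 1.44-fold. No paired analysis was possible because each group holds 1 library, beyond the matching of libraries across the other factor that the additive model already holds.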

Other observations

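All tests here were written before their values were seen, except the test setting dendritic cell markers against interferon and costimulation genes, which was chosen after its values were seen. The removal of the length and GC trend was added after seeing the data, as was the choice of the patterns. The precursor explanation was taken up because of neutrophil and cell cycle values already seen. A first version of its test, with bounds that seen values already met, was dropped for 6 genes whose values had not been seen. Granulocyte precursor genes outside the fixed neutrophil list were higher with si-Lnc-Dpf3 in both stimulations. Ms4a3, expressed in granulocyte-monocyte progenitors, rose by an average log2 change of 0.55 ± 0.06 (SE, limma adjusted p = 0.0018), and the granulocyte transcription factor gene Cebpe by 0.50 ± 0.07. The progenitor transcription factor gene Myb rose by 0.34 ± 0.08 (limma adjusted p = 0.048). Gfi1 (0.29), Serpinb1a (0.23) and Mgst1 (0.21) were higher without passing.

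Tricarboxylic acid cycle genes had knockdown medians of 0.09 under CCR7L (percentile 98.5) and 0.08 in unstimulated cells (percentile 97.4). In the average effect 1 of 21 rose, Idh3a by 0.33 ± 0.07, or 2 adjusted over the list alone, and the CCR7L medians were -0.03 under both siRNAs. Heat shock and oxidative stress genes had knockdown medians of 0.05 and 0.03, the latter negative with median-ratio scaling, and 1 of 16 rose, Gclm by 0.25 ± 0.06, while 1 fell, the metallothionein gene Mt2 at -0.32 ± 0.08, or 3 and 1 adjusted over the list alone. Lymphocyte markers, 7 of 17 measured, had knockdown medians of -0.13 and -0.14, and 0 passed over all genes and 1 lower adjusted over the list alone. Plasmacytoid dendritic cell markers, 6 of 10 measured, had medians of -0.04 and -0.09, and erythroid and stromal markers, 4 of 16 measured, 0.26 and -0.16, with 0 past limma in either list, over all genes or adjusted over the list alone.

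Neutrophil granule genes and cell cycle genes were both higher in the si-Lnc-Dpf3 libraries. A trend with transcript length or GC content would have brought the neutrophil median below 0.1 once removed, but it was 0.50 after and 0.46 before. More mature neutrophils would raise their abundant genes as much as the granule genes. The mature genes had a median 0.53 lower (difference -0.533, bootstrap 95% interval -0.848 to 0.279, 5 and 8 genes), and with so few genes this explanation cannot be told apart from the others. More granulocyte precursors in those cultures predicted a median over 0.1 in 6 precursor genes, and the smaller of their 2 medians was 0.283, with the average at percentile 100.0. Higher expression of the same genes within dendritic cells would give such values too, so the test cannot tell these apart. A larger share of granulocyte precursors is a candidate explanation for the neutrophil granule genes, and whether the cell cycle genes belong to those cells was not tested. An effect of the siRNA on their numbers, an effect on these genes within dendritic cells and a difference between single cultures may each apply and were not tested.

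Interferon response and costimulation genes were lower in both si-Lnc-Dpf3 libraries. Fewer dendritic cells would lower their markers alike, yet 11 conventional dendritic cell markers had an average median of -0.09 against -0.26 for the 59 interferon and costimulation genes, a difference of 0.164 (bootstrap 95% interval 0.077 to 0.269). Removing the length and GC trend left the pooled median at -0.251, from -0.257, and took the interferon median alone from -0.23 to -0.19. These values argue against that trend as the source of most of the lower values. The bootstrap interval resamples genes, not cultures, and this test was chosen after its values were seen. Of the 11 markers 9 were lower and 2 higher, and Itgax and Irf8 fell by more than the pooled median. The test therefore cannot settle whether a lower share of dendritic cells contributed. The knockdown, the sequence of either siRNA and a difference between single cultures may each account for the pattern, and none of these was tested.

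Oxidative phosphorylation and ribosomal protein genes had a positive interaction, and with glycolysis genes, which did not stand apart on their own (percentile 88.2), the pooled median was 0.133 over 116 genes. With the trend on transcript length and GC content removed, the pooled median was -0.01, and the medians were -0.01 for glycolysis, -0.04 for oxidative phosphorylation (percentile 2.38, from 100.0) and 0.01 for ribosomal proteins. A trend with length and GC content between the libraries is thus a likely source of the positive interaction of these groups, and the GC part is not confined to 1 library (rho with GC content of -0.219 for CCR7L under si-NC and 0.267 for the knockdown under CCR7L). A change in these genes that itself follows length or GC content would be removed in the same way and stays open.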
